A study of Homo sapiens with 6 samples.

How the data were processed

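The series measured messenger RNA in HepG2 cells grown as 2D cultures in plates (3 samples) and as 3D cultures in a hollow fiber bioreactor (3 samples). The groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, STAR 2.4.1d, Partek and the genome build hg38 were used. The annotation release, the counting settings, the read filters and the handling of strand are not given in the sources used here.

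The deposited table holds estimated counts per gene, as the authors made them, with 1 column per sample and no scaling to a common total. Of all values, 61.7% were whole numbers (with a tolerance of 0) and the others had fractions, whose origin is not given. The table lists 19846 genes with their chromosome, start, stop and gene type, and the lowest total of a gene over the 6 samples was 10, so genes below that total are not analysed here. Because strand handling is not given, reads of overlapping genes on opposite strands cannot be told apart. Values of near-identical gene copies are uncertain too, since how reads matching several genes were counted is not given.

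The estimated counts were rounded to whole numbers, which changed no library total by more than 25.0 counts. Total counts were 16270361, 16529945 and 17943513 in 2D replicates 1 to 3, and 9530795, 15897621 and 14522918 in 3D replicates 1 to 3. A count of 3, used as the floor for a gene with no counts, corresponds to between 0.167 and 0.315 CPM (counts scaled to a common library total) in these libraries. Floors cover counting error only. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom lay between 11.3 and 29.7.

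Differential expression was tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, a robust quasi-likelihood fit on the 6 samples with culture as the only term, and Benjamini-Hochberg adjustment over the 15314 genes kept. A gene was called at an adjusted p under 0.05. Fold changes are 3D over 2D, and levels are TMM-scaled CPM. The standard error of a log2 fold change was derived from its F statistic.

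In total 38 gene lists for liver functions, metabolism, growth, stress and other cell types were fixed before the data were examined, and 36 of them had at least 5 tested members. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Camera asks whether the members of a list rank above other genes, and it was repeated with a correlation estimated from the data. Fry was run as well. It asks instead whether the members change together in the same direction, without ranking them against other genes. The genes named were set by a rule fixed at the same time. The rule took the 8 largest increases and the 8 largest decreases among called genes with at least 5 CPM in the higher group and no overlap between groups. It also took up to 2 called genes per direction from each of the main lists, up to 1 from each of the other lists, at a level of 1 CPM or more, and 12 liver, growth and mesenchymal genes whatever their result. Not every gene the rule allows is named. Genes named outside it are said to be chosen after their values were seen, apart from members of tests that were written before these values were seen.

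Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, scaling without mitochondrial and the 50 most abundant genes, 2 other low-count filters, the replicate number as a block, and leaving out each sample. Added after seeing the data were a loess correction (span 0.5) for transcript length and GC content, the same with the block, a run on protein-coding genes only, and a run without 2 doubted libraries. These were 2D replicate 2, in which the median levels of the replication and of the G2 and M phase lists were the lowest of the 6 libraries, and 3D replicate 1, which had the fewest counts and lay apart on the second principal component. On the principal components 2D replicate 2 did not lie apart from its group. Transcript length and GC content came from GENCODE release 29. Of the genes in the table, 16155 matched it by symbol and a further 283 through an older symbol with overlapping coordinates, and 89.7% of the tested genes had both values.

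The scripts were tested on simulated data. In 5 simulations of the comparison of 3 against 3 libraries, each with 200 changed genes among 15037 to 15076 tested, the edgeR test recovered 20.3% of the genes changed 1.5-fold, 72.5% of those changed 2-fold and 94.2% of those changed 4-fold. Of its 670 calls 53 were false (7.91%). The false share was larger with DESeq2 (105 of 769 calls, 13.7%) and with the replicate block (82 of 706, 11.6%). Camera called all 10 simulated changed lists and 0 of 100 simulated unchanged lists, whose genes varied independently of each other, unlike genes of a real list.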

Results

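The expression profile of HepG2, a human liver tumour cell line, was measured after growth on flat plates (2D, 3 samples) and in an interwoven hollow fiber bioreactor (3D, 3 samples), in which cells sit among hollow fibres supplied with medium and gas. The comparison asks how gene expression differs between these cultures. Medium circulated through the bioreactor at 23.5 mL/min, and a feed of 2 mL/hour renewed it. The plates were seeded at 200000 cells per square centimetre, and their medium was changed every 2 days. The media also differed: EMEM on plates, and equal parts of EMEM and DMEM with 10% serum in the bioreactor. Culture form, medium and feeding thus differed together, so no difference below can be assigned to any of them alone. The serum content on the plates and the length of each culture are not given, so these may have differed too. Total counts ranged from 16270361 to 17943513 in 2D and from 9530795 to 15897621 in 3D. The labels do not say whether the samples of a group came from separate cultures or runs, so p-values measure the spread between these samples only, which may be technical.

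In 3D culture HepG2 cells had higher levels of 42 of 45 DNA replication genes, 19 of 26 glycolysis genes, 22 of 36 hypoxia response genes and 16 of 26 cholesterol genes. Levels were lower for 29 of 36 ATF4 target genes of the amino acid response and for 13 of 27 unfolded protein response genes. UHRF1, which maintains DNA methylation after replication, rose from 30.2 ± 11.6 to 125 ± 14.4 CPM (SD, n = 3 per group), and CA9, a carbonic anhydrase induced by low oxygen, from 2.36 ± 0.918 to 21.3 ± 9.19 CPM. SLC7A11, the cystine transporter, fell from 385.6 ± 43.2 to 66.9 ± 19.9 CPM. ALB and AFP, which encode the main adult and fetal serum proteins of the liver, and HNF4A, a master regulator of hepatocyte genes, did not pass the edgeR test, while ALB and AFP passed with DESeq2. Of 15314 genes tested with edgeR, 2910 were higher and 2697 lower in 3D, 1103 of them at least doubled and 687 at least halved.

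**Figure D1:**
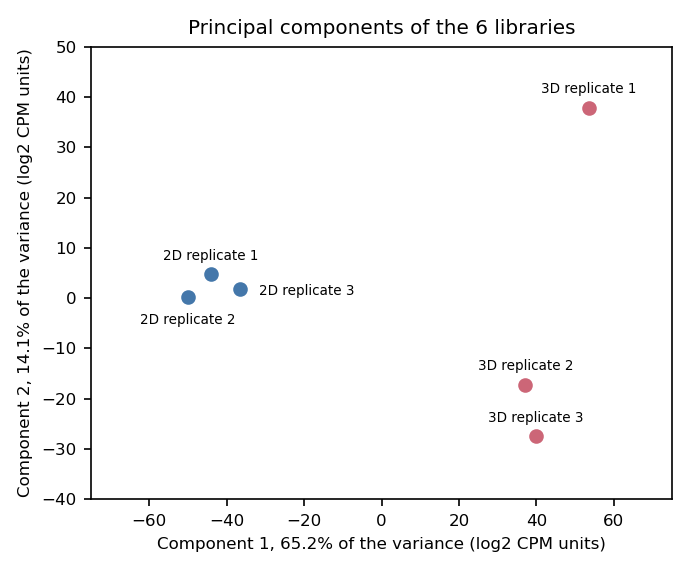
First and second principal components of log2 CPM over all tested genes, 1 point per library, blue for 2D and red for 3D. Component 1 (65.2% of the variance) separated the groups, and 3D replicate 1, the library with 9530795 counts, stood apart from the other 3D libraries on component 2 (14.1%).

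Genes of DNA replication and S phase rose in 42 of 45 cases and fell in 0 (45 and 0 adjusted over the list alone), with a median log2 fold change of 1.33. UHRF1 rose 4.13-fold (log2 2.05, SE 0.25, edgeR adjusted p = 0.000395), and TK1, the thymidine kinase of dividing cells, 5.45-fold. Of 40 genes of G2 and M phase, 24 rose and 0 fell (25 and 0 adjusted over the list alone), among them PTTG1, the securin, at 3.35-fold and AURKB, a mitotic kinase, at 2.96-fold. The camera adjusted p was 4.5e-16 for the replication list, with an adjusted p = 0.602 with an estimated correlation, and 1.13e-06 for the G2 and M list, with an adjusted p = 0.646 with an estimated correlation and 0.134 with fry. MKI67, a marker of cycling cells, was at 145.7 ± 80.6 CPM in 2D and 220.4 ± 37.4 CPM in 3D (edgeR adjusted p = 0.254). Without 2D replicate 3, where MKI67 stood at 234 CPM, its log2 difference was 1.11, at an edgeR adjusted p = 0.00578. No other run without a single library called MKI67. The replicate block with length and GC content corrected did call it (edgeR adjusted p = 0.0343). Replication-dependent histone genes went the other way, with 0 of 15 higher and 5 lower (the same numbers adjusted over the list alone) and a median of −0.76. HIST2H2BE, a histone H2B gene with near-identical copies, fell from 27.6 ± 9.12 to 5.99 ± 3.65 CPM. For the histone list the camera adjusted p was 0.0235, with an adjusted p = 0.602 with an estimated correlation. As a class, transcripts of replication-dependent histone genes mostly lack a poly(A) tail, so their levels may also depend on how the RNA was selected. Whether this holds for the single genes that fell was not tested. A fall in these levels need not be a fall in histone expression.

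Of 36 hypoxia response genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone), and of 26 glycolysis genes 19 rose and 1 fell (19 and 2). CA9 (chromosome 9, 35673856 to 35681159, hg38) rose 8.98-fold, and EGLN3, an oxygen-sensing prolyl hydroxylase, rose 7.62-fold. PFKFB3 and PFKFB4, enzymes that set the level of the main activator of glycolysis, rose 9.16-fold and 7.24-fold. HK2, a hexokinase on both lists, fell to 212.2 ± 33.7 CPM from 348.4 ± 34.0 CPM (log2 −0.71, SE 0.14). The median log2 fold change was 0.77 for hypoxia genes (camera adjusted p = 7.34e-05, and adjusted p = 0.646 with an estimated correlation and 0.0643 with fry). For glycolysis genes it was 1.17 (camera adjusted p = 7.99e-07, and adjusted p = 0.602 with an estimated correlation). The gluconeogenesis and glycogen list was not called (10 of 17 rose, 4 fell, camera adjusted p = 0.113), although fry called it higher (adjusted p = 0.00768). G6PC, the catalytic subunit of glucose-6-phosphatase, rose 4.36-fold, while PPARGC1A, a coactivator of fasting genes, fell from 76.1 ± 13.1 to 15.1 ± 2.54 CPM. Of 55 nuclear genes of oxidative phosphorylation, 39 rose and 0 fell (44 and 0 adjusted over the list alone), with a median log2 fold change of 0.60 and ATP5D, a subunit of ATP synthase, at 2.60-fold. Their camera adjusted p was 2.04e-09, with an adjusted p = 0.602 with an estimated correlation. With length and GC content corrected together 26 rose and 1 fell, with a median of 0.34 and ATP5D at a log2 fold change of 0.76. Of 13 mitochondrially encoded genes, 0 rose and 2 fell (camera adjusted p = 0.679, and 0.00553 with length and GC content corrected).

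**Figure D2:**
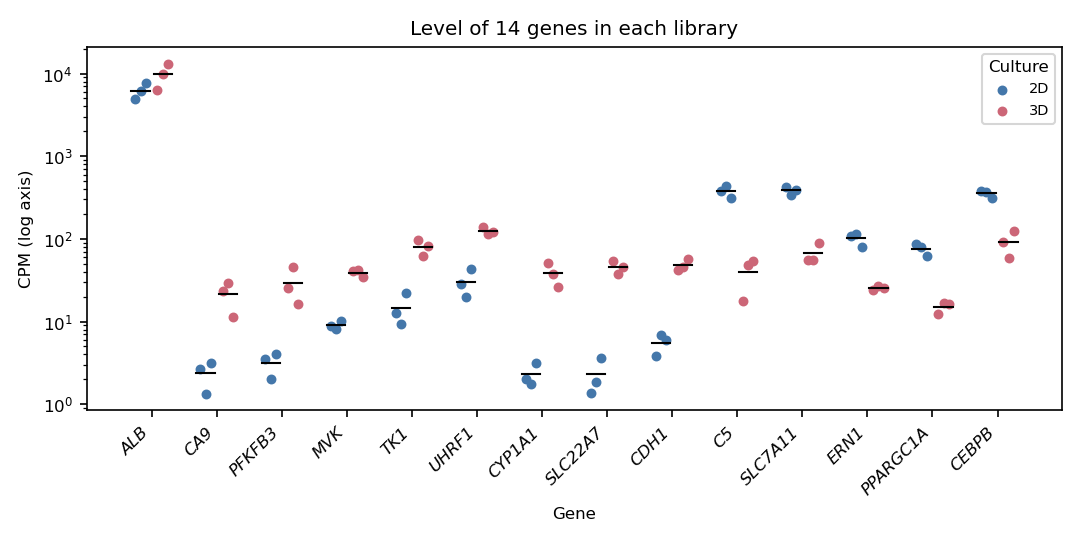
CPM of 14 genes (log axis), 1 point per library, blue for 2D and red for 3D, with a black line at the mean of each group of 3. The groups do not overlap for 13 of the genes, and they overlap for ALB.

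Cholesterol synthesis and uptake genes rose in 16 of 26 cases and fell in 1 (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.92. MVK and MVD, both enzymes of the mevalonate pathway, rose 4.29-fold (log2 2.10, SE 0.15, edgeR adjusted p = 1.89e-05) and 3.21-fold. The camera adjusted p of this list was 3.08e-05, with an adjusted p = 0.646 with an estimated correlation. Fatty acid synthesis genes were not called as a list (9 of 18 rose, 2 fell, camera adjusted p = 0.114, and 0.0487 with length and GC content corrected). FADS2, a fatty acid desaturase, rose 3.74-fold and ACSL3, an acyl-CoA synthetase, fell from 477.1 ± 96.9 to 217 ± 54.0 CPM. Of 28 genes of fatty acid oxidation and PPAR alpha targets, 11 rose and 5 fell (camera adjusted p = 0.117, and 0.0372 without 3D replicate 1). ANGPTL4, a secreted lipase inhibitor that is on the hypoxia list too, rose 7.14-fold. PPARA itself fell from 82.3 ± 4.47 to 44.5 ± 2.87 CPM (log2 −0.89, and −0.52 with length and GC content corrected).

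ATF4 target genes of the amino acid response fell in 29 of 36 cases and rose in 2 (the same numbers adjusted over the list alone), with a median log2 fold change of −0.95. ALDH1L2, a mitochondrial folate enzyme, fell from 17.2 ± 2.61 to 2.27 ± 1.06 CPM (log2 −2.88, SE 0.28, edgeR adjusted p = 6.8e-05), and SLC7A11 had a log2 fold change of −2.52 (SE 0.20). The camera adjusted p was 4.91e-11, with an adjusted p = 0.602 with an estimated correlation. Of 27 unfolded protein response genes 13 fell and 2 rose (14 and 4 adjusted over the list alone), with a median log2 fold change of −0.51, and ERN1, the stress sensor IRE1, fell from 101.4 ± 19.5 to 25.4 ± 1.21 CPM. Their camera adjusted p was 0.00221, with an adjusted p = 0.646 with an estimated correlation. Immediate early genes, which respond within minutes to growth factors or handling, fell in 12 of 27 cases and rose in 3 (14 and 3 adjusted over the list alone), with a median of −0.76. Their camera adjusted p was 0.00868, with an adjusted p = 0.646 with an estimated correlation. Without 2D replicate 2 and 3D replicate 1 together the adjusted p was 0.0716 for each of these last lists, with a median of −0.28 for the unfolded protein response and −0.60 for immediate early genes. NRF2 and oxidative stress genes rose in 19 of 33 cases and fell in 3 (19 and 4 adjusted over the list alone). HMOX1, heme oxygenase, rose 2.74-fold, while SLC7A11, which is on this list too, fell (log2 −2.52). The camera adjusted p of the NRF2 list was 0.00134, with an adjusted p = 0.602 with an estimated correlation. Its median log2 fold change of 0.64 was 0.31 with length and GC content corrected.

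**Figure D3:**
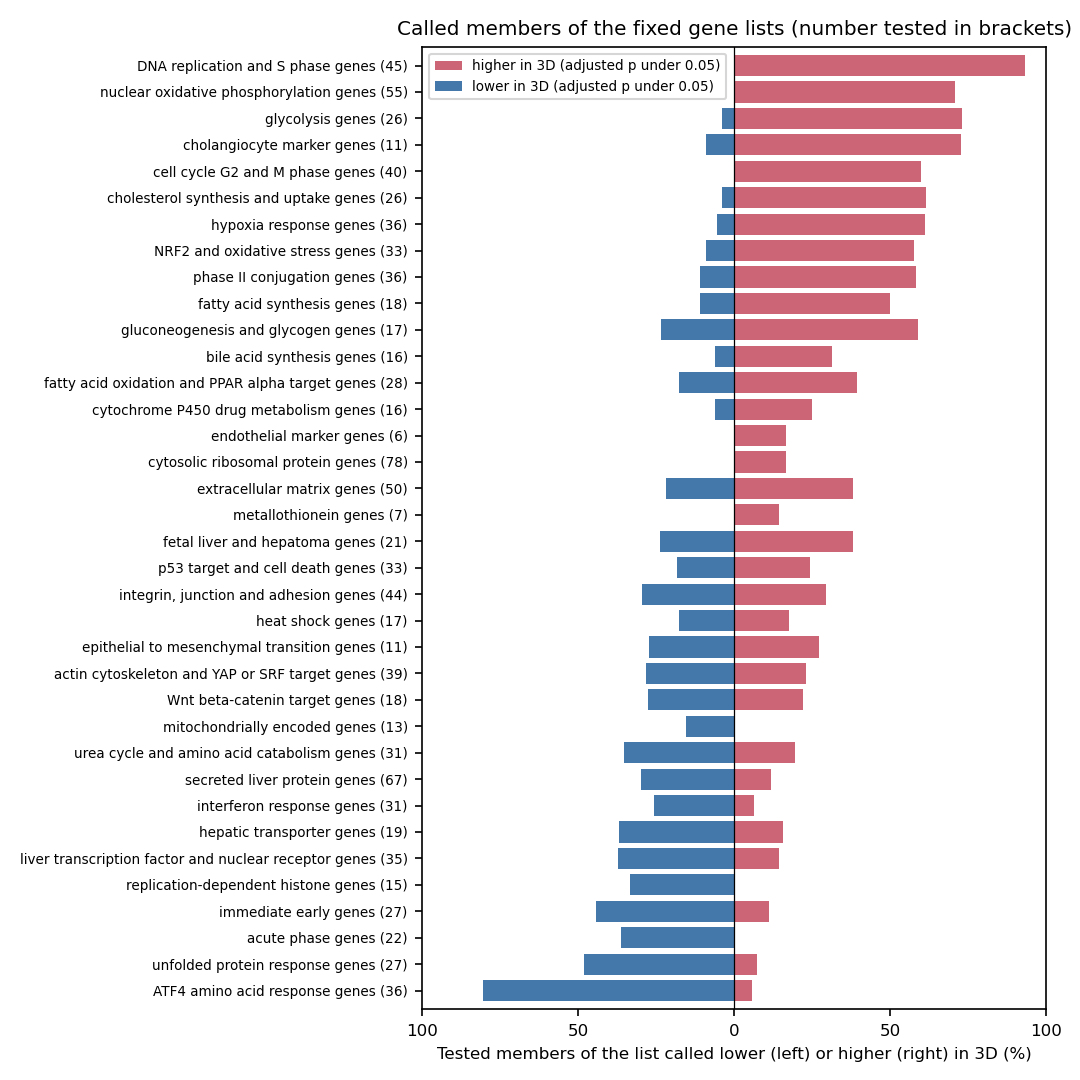
Percentage of tested members called higher (red, right) or lower (blue, left) in 3D for the 36 fixed lists, with the number tested in brackets. DNA replication stands at the top with 42 of 45 higher, and ATF4 targets at the bottom with 29 of 36 lower.

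Among genes of drug handling, CYP1A1 (chromosome 15, 74719542 to 74725610), an enzyme that oxidises aromatic hydrocarbons, rose from 2.29 ± 0.719 to 38.4 ± 12.8 CPM (16.6-fold, log2 4.05, SE 0.30, edgeR adjusted p = 2.92e-05). Cytochrome P450 genes did not move as a list: 4 of 16 rose and 1 fell, with a median log2 fold change of −0.09 and a mean of 0.26 (camera direction up, adjusted p = 0.809). CYP2D6 was at 1.48 ± 0.596 CPM in 2D and 0.995 ± 0.136 CPM in 3D (edgeR adjusted p = 0.285). CYP2B6, CYP2E1 and CYP3A4 had at most 8 counts in any library and were too low to test, and CYP1A2 and VIM were not analysed here. Phase II conjugation genes rose in 21 of 36 cases and fell in 4 (23 and 5 adjusted over the list alone), with GSTA1, a glutathione transferase with a near-identical copy, at 5.78-fold. Their camera adjusted p was 0.00105, with an adjusted p = 0.602 with an estimated correlation. Of 19 hepatic transporter genes 3 rose and 7 fell (camera adjusted p = 0.129). SLC22A7, an organic anion transporter, rose 19.6-fold, and ABCB1, the multidrug exporter, fell from 120.7 ± 22.4 to 52.6 ± 13.2 CPM.

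Liver identity genes changed in both directions. Of 35 liver transcription factors and nuclear receptors, 5 rose and 13 fell (the same numbers adjusted over the list alone); CEBPB, an inducible liver regulator, fell from 354.2 ± 37.5 to 91.8 ± 33.7 CPM, and NR1I2, a nuclear receptor that senses foreign compounds, rose 1.79-fold. Their camera adjusted p was 0.0475, with an adjusted p = 0.602 with an estimated correlation. It was 0.0560 without 2D replicate 1 and 0.113 without 3D replicate 2. The camera call was also lost with a filter of 1 CPM in 3 samples (adjusted p = 0.0503) and on protein-coding genes only (0.0595). With fry the adjusted p of this list was 0.00392. With length and GC content corrected the camera adjusted p was 0.00670. The median log2 fold change of this list was −0.16, and −0.18 without 3D replicate 2. HNF4A stood at 353.8 ± 20.2 CPM in 2D and 324.9 ± 23.8 CPM in 3D (edgeR adjusted p = 0.453). ALB was at 6237 ± 1322 CPM in 2D and 9849 ± 3472 CPM in 3D (edgeR adjusted p = 0.0698), and AFP at 6840 ± 1181 CPM and 9410 ± 1787 CPM (0.0852). Both were called higher by DESeq2 (adjusted p = 0.0150 for ALB and 0.0319 for AFP), and by edgeR without 3D replicate 1, at log2 differences of 0.88 and 0.60 (adjusted p = 0.00576 and 0.0183). In simulated data a larger share of calls was false with DESeq2 than with edgeR. AFP was also called with length and GC content corrected (edgeR adjusted p = 0.0322). Of 67 secreted liver protein genes 8 rose and 20 fell (camera adjusted p = 0.129, and 0.00914 without 3D replicate 3 and 0.00482 with length and GC content corrected). C5, complement component 5, fell from 376.6 ± 61.1 to 40.0 ± 19.3 CPM (log2 −3.22, SE 0.38). Acute phase genes fell in 8 of 22 cases and rose in 0 (9 and 0 adjusted over the list alone), and their camera adjusted p was 0.0161, with an adjusted p = 0.646 with an estimated correlation and 0.139 without 3D replicate 1. Lists for fetal liver (8 of 21 rose, 5 fell), bile acid synthesis (5 of 16 rose, 1 fell) and amino acid catabolism (6 of 31 rose, 11 fell) were not called, although the last was called lower with length and GC content corrected (camera adjusted p = 0.0206).

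Structural and surface genes also went both ways. CDH1, the epithelial adhesion protein E-cadherin, rose from 5.57 ± 1.51 to 48.0 ± 7.99 CPM (log2 3.10, SE 0.21), and COL1A1, a fibrillar collagen, from 1.26 ± 0.739 to 13.8 ± 6.62 CPM. CEACAM1 and ITGA2, both surface adhesion proteins, fell from 177.4 ± 19.8 to 45.7 ± 3.82 CPM and from 211.5 ± 28.9 to 74.0 ± 24.0 CPM. As lists, extracellular matrix (19 of 50 rose, 11 fell), adhesion (13 of 44 rose, 13 fell) and actin or YAP target genes (9 of 39 rose, 11 fell) were not called. The adhesion list had a median of −0.04 and a mean of 0.04, with a camera direction of down. The epithelial to mesenchymal transition list (3 of 11 rose, 3 fell) had a median of 0.13 and a mean of 0.30 with a camera direction of down, and the Wnt list (4 of 18 rose, 5 fell) a median of 0.02 and a mean of −0.04.

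Among markers of other cell types, 8 of 11 cholangiocyte genes rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.00215, and adjusted p = 0.602 with an estimated correlation). KRT19, a bile duct keratin chosen after its values were seen, rose from 70.9 to 226.8 CPM, and SOX9, a bile duct transcription factor, fell from 370.0 to 271.5 CPM (log2 −0.45, SE 0.12, edgeR adjusted p = 0.0117). CD68 rose 4.21-fold among 3 tested blood and macrophage genes, of which 0 fell. Of 4 fibroblast genes 1 rose and 2 fell, with PDGFRB from 10.6 ± 3.39 to 3.21 ± 0.305 CPM. Of 6 endothelial genes 1 rose (camera adjusted p = 0.114, and 0.0138 without 3D replicate 3). Lists for heat shock (3 of 17 rose, 3 fell), metallothioneins (1 of 7 rose), p53 targets (8 of 33 rose, 6 fell) and interferon response (2 of 31 rose, 8 fell, camera adjusted p = 0.113) were not called. Without 3D replicate 3 the adjusted p of the interferon list was 0.0109, and with length and GC content corrected 0.00116. Adjusted over the list alone, the lists not called had the counts given here and above, except for 12 fatty acid oxidation genes higher, 0 metallothioneins higher, and 9 transporter, 21 secreted protein, 13 amino acid catabolism, 15 adhesion, 4 transition, 7 p53 target, 4 interferon, 1 mitochondrial and 1 blood cell genes lower.

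The largest increases included genes without a count in 2D. ALPPL2 (chromosome 2, 232406843 to 232410714), a placental-type alkaline phosphatase whose reads are hard to tell from those of its copy ALPP, had 0 counts in the 2D libraries and 40.1 ± 20.8 CPM in 3D, at least 214-fold above a floor of 3 counts per library. HOXC12 (chromosome 12, 53954834 to 53958956), a homeobox gene, had 0 counts in 2D and 5.30 ± 1.78 CPM in 3D, at least 28.2-fold above that floor. PMEPA1, an inhibitor of TGF-beta signalling, rose from 0.172 ± 0.167 to 26.2 ± 15.2 CPM. Among the largest decreases, KLHDC7B (chromosome 22, 50548033 to 50551023) fell from 31.4 ± 6.39 to 0.910 ± 0.219 CPM (log2 −5.07, SE 0.25, edgeR adjusted p = 2.77e-06), and PLIN5, a lipid droplet protein, from 12.4 ± 2.86 to 1.68 ± 0.347 CPM.

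Fold changes moved with transcript length and with GC content. Over 12266 protein-coding genes the median log2 fold change was 0.39 in the shortest of 10 equal groups and −0.42 in the longest, with a Spearman correlation across genes, which are not independent replicates, of −0.386 with length and 0.331 with GC content. The calls moved too: 504 genes rose and 44 fell in the shortest group, and 71 rose and 601 fell in the longest. The correction changed length and GC content together, so it does not separate them. Cytosolic ribosomal protein genes rose in 13 of 78 cases and fell in 0 (2 and 0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0104, and adjusted p = 0.861 with an estimated correlation). With length and GC content corrected, their median was −0.068 (adjusted p = 0.281), and the call was also lost without 2D replicate 3 (0.270), 3D replicate 2 (0.05003) or 3D replicate 3 (0.245).

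**Figure D4:**
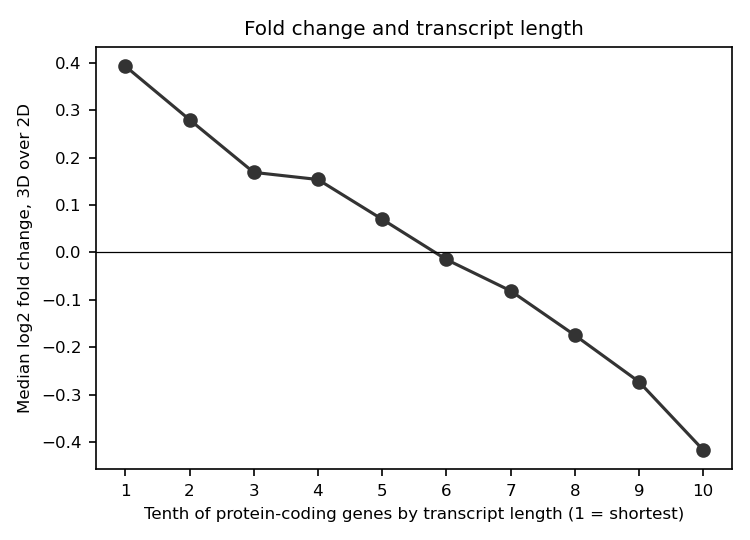
Median log2 fold change (3D over 2D) of protein-coding genes in 10 groups of rising transcript length, 1 point per group. The medians run from 0.39 in the shortest group to −0.42 in the longest.

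The groups did not overlap for 50.5% of the tested genes, against 10% by chance, and without 2D replicate 1 the number of higher genes was 1938. The camera calls rest on the preset correlation: 10 lists were called higher and 6 lower, and regrouping the libraries across cultures gave up to 13 called lists in a direction.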

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

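The length and GC correction, its run with the replicate block, the run on protein-coding genes and the run without both 2D replicate 2 and 3D replicate 1 were chosen after seeing the data. Numbers of called genes stayed within 1.5 times the reported ones under every scaling, filter and test tried, and in the runs without a library, with the exception of higher genes without 2D replicate 1 (1938, leave-out range 1938 to 2817 against 2910). That run has fewer samples. With an estimated inter-gene correlation camera called 0 lists higher and 0 lower, with 1 list at an unadjusted p under 0.05; the estimated correlations were large in lists such as G2 and M phase (0.910). Fry called 8 lists higher and 2 lower: the hypoxia, histone and unfolded protein response lists (each at an adjusted p = 0.0643), G2 and M phase (0.134), acute phase (0.119), immediate early (0.165) and ribosomal protein lists (0.338) lost their call, and gluconeogenesis and glycogen gained one (higher, 0.00768). With length and GC correction 10 lists were lower, likewise 10 with the replicate block and length and GC correction, and 3 lists were lower without both 2D replicate 2 and 3D replicate 1; the cause was not tested. Under the length and GC correction the gained lists were secreted liver proteins, amino acid catabolism, interferon response and mitochondrially encoded genes (lower) and fatty acid synthesis (higher). The ribosomal protein list reversed to a median log2 fold change of −0.068 with the correction and to −0.076 with the block as well, neither called.

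No pairing by replicate number was seen. Deviations from the group means correlated at 0.053, −0.0092 and −0.078 between libraries with the same number, and not every sample correlated best with its own number. With so few libraries per group this cannot exclude that samples with the same number were paired. With the replicate block edgeR called 2747 genes higher and 2611 lower, with 10 lists higher and 5 lower; the list of liver transcription factors missed the threshold (camera adjusted p = 0.0549), and ALB passed it (edgeR adjusted p = 0.0397). Of the reported calls, the length and GC correction shared 2123 higher and 1863 lower genes, and DESeq2 2779 and 2610. A 1.5-fold change was mostly missed in simulated data, each set with 200 changed genes. The real comparison called 2910 genes higher and 2697 lower, so its cut on the unadjusted p was less strict. The simulated share therefore does not carry over to the real comparison.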

Other observations

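The genes in this paragraph were chosen after their values were seen. TXNIP and ARRDC4, arrestin-family genes induced by intracellular glucose, rose from 22.2 to 95.9 CPM and from 1.60 to 10.5 CPM (edgeR adjusted p = 0.00998 and 0.000453). PKLR, the liver pyruvate kinase, rose from 4.57 to 15.4 CPM. IGF2, a fetal growth factor and among the most abundant transcripts, rose from 6525 to 17898 CPM (log2 1.46, SE 0.20). AGPAT2, an enzyme of phospholipid and triglyceride synthesis, rose from 2.44 to 43.7 CPM (log2 4.15, SE 0.31). NODAL, an embryonic signal of the TGF-beta family, rose from 0.0572 to 1.67 CPM, and SMAD7, a feedback inhibitor of that family, from 18.1 to 36.5 CPM. ASNS and TRIB3, both ATF4 targets, fell from 178.8 to 56.7 CPM and from 503 to 187.5 CPM. The histone genes HIST1H2AC, HIST1H2AG, HIST1H2BD and HIST2H4A fell with HIST2H2BE while replication genes rose, at log2 fold changes of −1.67, −1.83, −1.12 and −1.55. Levels of these histone genes, too, may depend on how the RNA was selected.

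The tests of transcript length, of depth, and of adherent cells by summed markers were chosen only after the results were seen. The first pattern is the fall of fold changes with transcript length. As the whole cause of the list calls, the trend with length and GC content together is argued against by the correction of both, under which 0 of the 15 called lists other than ribosomal proteins lost their call. For the ribosomal protein list the trends with length and GC content together may account for the call, since the corrected median was −0.068 (−0.076 with the block); fold changes rose with GC content (Spearman correlation 0.331), both were corrected at once, and neither can be credited alone. A difference in RNA or library quality stays open: the largest difference of slopes on length between libraries of a group was 0.551 of the smallest difference between groups, which does not decide it, and a quality difference shared by all libraries of a group is confounded with culture. Slopes on GC content (log2 per percentage point) were −0.0114, −0.0105 and −0.0135 in 2D replicates 1 to 3. In 3D replicates 1 to 3 they were 0.0251, −0.0018 and 0.0121. On GC content, 3D replicates 1 and 2 thus lay further apart than 3D replicate 2 and any 2D library. The culture itself, as a biological explanation, was not tested.

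The second pattern is genes without counts in 2D and with counts in 3D: in 5 genes (ALPPL2, CST1, HOXC12, R3HDML and SPOCK1) all 2D libraries had 0 counts and every 3D library at least 1 CPM, and 0 genes showed the opposite (79 and 28 genes for a mean under 0.5 CPM in place of 0 counts). Lower depth in 2D is argued against, since the smallest 2D total was 1.02 times the largest 3D total. For adherent cells of another line or mesenchymal type, 7 markers were taken for low 2D levels (CAV1, CAV2, CD44, THY1, MSN, ANXA1 and EMP1). Their sum was 2.43 ± 1.40 CPM in 2D and 1.62 ± 0.846 CPM in 3D (SD, n = 3). The ratio was 0.665, beside 40.1 CPM of ALPPL2. This argues against such cells only as far as these markers read them. Of 4 tested fibroblast genes, 1 rose (COL1A1, from 1.26 to 13.8 CPM) and 2 fell. Other foreign cells may still contribute. Of the 2 tested markers under 2 CPM in 2D, EMP1 was not called and LAPTM5, a blood cell gene, rose from 0.904 to 9.41 CPM. The median log2 fold change of both was 1.96 (SE 1.78). The share called higher met the bound set before the data on these markers were seen. With 2 markers 1 call was enough for that, so this test cannot decide. Markers of one cell type, here named after their values were seen, moved apart: the blood gene CORO1A rose from 2.11 to 7.76 CPM, while LCP1 was at 4.18 and 4.67 CPM (edgeR adjusted p = 0.650) and ARHGDIB and RAC2 had at most 6 counts in any library, and SFN of squamous cells rose from 5.32 to 26.0 CPM, while KRT5 had 4, 12 and 0 counts in 2D and 0 in every 3D library; TUBB3 of neural cells rose from 91.6 to 195 CPM, and activation of these genes by the culture was not tested.

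The last pattern is the rise of CYP1A1, for which activation of the aryl hydrocarbon receptor may be an explanation. Its direct targets AHRR and TIPARP had not been looked at before: AHRR was at 0.776 CPM in 2D and 2.15 CPM in 3D (edgeR adjusted p = 0.130), and TIPARP had a log2 fold change of −0.016 (SE 0.20, adjusted p = 0.959). ALDH3A1, UGT1A1 and NQO1, also targets and named after their values were seen, rose from 0.196, 0.143 and 287.6 to 2.21, 3.34 and 560.4 CPM. However, NQO1 is an NRF2 target too. NFE2L2 and SLC7A5, taken as targets as well and likewise named after their values were seen, did not rise. Their log2 fold changes were −0.43 and −0.20 (edgeR adjusted p = 0.0588 and 0.267). The tables leave this hypothesis open, since TIPARP neither rose nor fell beyond its error, and the medium differed between the groups along with the culture.

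The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split called 2910 genes higher, 2697 lower, 1103 at least doubled and 687 at least halved with edgeR, and the highest of the other splits was 0 for each (1 of 10 splits as large). In those other splits edgeR gave at most 268 genes at an unadjusted p under 0.05, against 7116 in the real split, and DESeq2 called at most 2. For the lists, a split was counted by its larger direction, since which side is called higher is arbitrary in a mixed split: 4 of the 10 splits, the real one included, reached the 10 lists called higher and 7 reached the 6 called lower. The highest other split had 13 lists in either case, and each of the other splits mixed libraries of both cultures. In a mixed split the difference between cultures adds to the spread within each group, which lowers the number of called genes. The low gene counts of the other splits therefore do not measure what unrelated libraries would give.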
